A study of Mus musculus with 16 samples.

How the data were processed

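Bulk CEL-seq and single-cell CEL-seq2 libraries of mouse stem cells, blastocysts, blastoids and trophospheres were used, 10 bulk and 6 single-cell libraries. The authors deposited 1 table of genes by wells per library. Alignment with BWA 0.6.2-r126 to mm10 is credited to the submitters' processing notes, which do not name the counting tool. For the bulk libraries the deposited values were counts of reads per gene and well, all whole numbers. For the single-cell libraries the deposited values were transcript counts, corrected by the authors for molecular barcodes that occur more than once with a natural logarithm: they inverted to whole barcode counts with 4096 possible barcodes, with a largest deviation of 4.09e-12 from a whole number. The conditions of the bulk wells came from a table of the submitters. It described 15 wells used here; 17 further wells with reads in the blastocyst and stem cell libraries had no described condition and entered no comparison. Described wells under 10% of the median total of their library would have been left out, and none was.

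Levels in CPM were computed from the deposited counts, divided in comparisons of single wells by the total of the well times its TMM scaling factor, or from the summed barcode counts of kept cells. Intervals of levels are exact Poisson 95% intervals, those of shares are Clopper-Pearson intervals, and intervals of list medians come from 1000 Poisson draws. They cover counting error only, so a gene with few reads has a wide interval at 49431 reads for E3.5 blastocysts and a narrow one at 5963823 reads for a Nodal library. No mitochondrial genes were in any file.

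Bulk groups of 2 were compared in log2 CPM with limma 3.58.1 (voom and empirical Bayes) in R 4.3.3, with TMM scaling computed in own code, an expression filter (10 counts, total 15) and Benjamini-Hochberg adjustment at 0.05 over all tested genes. The stem cell fit had 2 residual degrees of freedom and the trophosphere fit 4. A quasi-likelihood test had been chosen before the data were examined, but could not be run here, and limma voom took its place after voom and limma-trend had been tested on simulated data. With no change simulated, 5.33% of trophosphere genes had an unadjusted p under 0.05 by voom and 8.76% by limma-trend. On simulated data voom found 94.7% of 4-fold and 40.8% of 2-fold changes in stem cells, 94.2% and 69.1% in trophospheres, and 3.94% and 10.5% of the called genes were false. The simulations gave all genes and libraries of a design 1 common dispersion. They leave out genes or libraries of larger spread, so these rates may not hold for the data. Both ligands and their interaction were fitted in 1 model of 8 libraries. Shared controls were weighed against 100 simulations.

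The 31 gene lists were fixed before the data were examined. In bulk fits they were tested with camera at a preset correlation of 0.01, and again with camera at an estimated correlation and with fry. With an estimated correlation camera has at most the residual degrees of freedom of the fit, 2 for stem cells and 4 for trophospheres. Few lists can pass it at that number. For comparisons of single wells the median log2 ratio of members past the expression filter (10 counts, total 15) was computed. For single-cell libraries it was that of members with at least 10 CPM. In both, 5 CPM was added before the ratio, and 10000 random lists matched in 20 expression bins were computed beside it. Named genes were the 12 largest differences in each direction among tested genes with an average log2 CPM of at least 4, or among single-cell genes with at least 50 CPM whose interval lay beyond 2-fold, and 2 to 4 members of each list.

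Wells with at least 2000 transcripts were kept as cells. Cells were scaled to 10000 counts, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 were used, with scanpy 1.11.5, leidenalg 0.10.2 and igraph 0.11.9. A marker led a cluster when it had at least 10 CPM and stood 2-fold over other clusters. A cluster took the name of a cell type when at least 3 markers of that type led it. It stayed unnamed when 2 times the leading markers of the next type exceeded those of the first. The same held when another type had more markers among its top 10 genes, or when it was of low depth without an own marker there. Parts of this rule were set after the clusters had been seen. In simulated data 95.6% of the single-cell intervals held the true ratio. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, and gene positions came from the RefSeq annotation of mm10.

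Transcripts of other cell types were counted with lists of 11 fibroblast, 12 immune and 10 mammary genes, of which 8 of the mammary genes were in the files. Alternatives covered scaling, filter, test, each replicate left out, reads thinned to equal depth, the medium as a term, cell depth limits of 1000 and 4000 transcripts, cells over 2.5 times the median depth left out, 1 or 20 CPM added, means over cells and Leiden resolutions of 0.3 and 1. A term for the library could not be fitted, since each trophosphere well was a library of its own.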

Results

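RNA of mouse stem cells, blastocysts, blastoids (blastocyst-like structures grown from embryonic and trophoblast stem cells) and trophospheres (hollow structures grown from trophoblast stem cells alone) was measured in 10 bulk and 6 single-cell libraries. Of the bulk wells with a stated condition, 1 well each held blastoids, blastocysts of embryonic day E3.25 and blastocysts of day E3.5. In the stem cell library 1 well each held trophoblast stem cells in TX medium, trophoblast stem cells in blastoid medium, embryonic stem cells in 2i medium and embryonic stem cells in blastoid medium. Trophospheres were grown without a ligand, with Bmp4, with Nodal or with both ligands, with 2 libraries per condition. The single-cell libraries held trophoblast (trophectoderm) stem cells and embryonic stem cells, each grown in 3D or in 2D with 1 library per culture, and dissociated blastoids with 2 libraries.

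Reads on genes came to 961896 for blastoids, 258686 for E3.25 blastocysts and 49431 for E3.5 blastocysts. Trophoblast stem cells held 1367570 reads in TX medium and 1543831 in blastoid medium, and embryonic stem cells held 1853229 in 2i and 1260833 in blastoid medium. Control trophospheres held 1180093 and 1466851 reads, Bmp4 trophospheres 3521934 and 4839866, Nodal trophospheres 5963823 and 5524026, and trophospheres with both ligands 3867352 and 4298649. Of 384 wells per single-cell plate, the kept cells numbered 337 for trophoblast stem cells in 3D, 301 in 2D, 288 for embryonic stem cells in 3D, 329 in 2D, and 294 and 279 for the blastoid libraries. Their median transcripts per cell were 38433, 35527, 36826, 38310, 31377 and 36819 in that order. Intervals of levels, ratios, shares and list medians below cover counting error only. The bulk values are reads rather than molecules, so intervals of bulk wells take each read as independent and may be too narrow. Groups of 1 well or 1 library have no replicate error, so no test of difference was made for them.

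How far the transcriptome of blastoids lay from that of blastocysts was asked in single wells. Blastoids held less mRNA of Pou5f1, the core pluripotency factor, with 169.8 CPM (95% interval 144 to 199), against 1439 (1292 to 1598) at E3.25 and 531 (358 to 758) at E3.5. Keratins of the trophectoderm were at or above the blastocyst level: Krt18 stood at 5281 CPM against 2689 and 4533, and Krt8 at 3557 against 2191 and 2550. Igf2, an imprinted growth factor, stood at 2277 CPM (2180 to 2378) in blastoids, at 148 (104 to 205) at E3.25 and at 1469.7 (1171 to 1822) at E3.5. Across 4590 genes the blastoid profile had a Spearman rho of 0.670 with E3.25 and 0.710 with E3.5. It was 0.787 with trophoblast stem cells in TX medium and 0.593 with embryonic stem cells in 2i. With these stem cells in blastoid medium it was 0.793 and 0.690. The blastocyst wells, with 258686 and 49431 reads, had a rho of only 0.591 with each other. The wells differed in depth, so these values do not rank them by likeness to blastoids. Genes are not independent replicates.

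Of 3746 genes, 5 were higher in blastoids than at both blastocyst stages by more than 2-fold over the whole interval, and 43 were lower. These counts cannot be compared with each other, since the wells held 961896 reads for blastoids and 49431 for E3.5 blastocysts. A gene with few reads at E3.5 has a wide interval there and passes less easily as higher in blastoids. The 5 higher were Syde1 (775 CPM against 90.4 and 159), Bcr (142 against 28.8 and 0), Sct, which encodes secretin (1905 against 107 and 443), Cyb5r3 (916 against 263 and 248) and the tight-junction claudin Cldn6 (3054 against 1131 and 460.4). Among the 43 lower were the germ cell and pluripotency genes Dppa2 (18.99 CPM against 275 and 195) and Dppa3 (2.23 against 366 and 53.1). Lower as well were Calcoco2 (11.2 against 2804 and 389.5), Crxos1 (12.3 against 2972 and 177), Pramel6 (1.12 against 139.8 and 88.5), Whamm (12.3 against 164 and 248), Pigp (1.12 against 57.6 and 53.1) and Gm9376 (2.23 against 1098 and 53.1). Csta, Slc1a1, Timd2 and the alkaline phosphatase gene Alppl2 had 0 reads in blastoids, which allows up to 4.12 CPM, against 53.4, 78.1, 526 and 1373 CPM at E3.25 and 53.1 CPM, or 3 reads, for each of them at E3.5.

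Naive pluripotency genes stood lower in blastoids than at E3.25 in 13 of 16 measured members, with a median log2 ratio of -1.42 (-1.87 to -1.25), and lower than at E3.5 in 13 of 16, with a median of -0.43 (-0.998 to -0.07). Klf5 stood at 299 CPM against 1949 and 354, and Dppa5a at 346 against 909 and 478. Trophectoderm genes went both ways: Lgals3 stood at 1176 CPM against 111 and 637, whereas Cdx2, which specifies trophectoderm, stood at 100.5 (80.8 to 124) against 349 (279 to 432) and 354 (216 to 547). Trophoblast progenitor genes split as well, with the homeobox gene Rhox6 at 1199.6 CPM against 94.6 and 407 and Eomes at 77.1 against 136 and 443. Genes that mark trophoblast differentiation included Rhox9 at 572 CPM against 28.8 and 354, and Hand1 at 83.8 against 0 at both stages, where a count of 0 allows up to 15.2 and 65.3 CPM. BMP targets were higher than at E3.25 in 4 of 5 members (median 2.51, 1.37 to 3.71) and than at E3.5 in 3 of 5 (median 1.19, -0.26 to 3.38), with Id1 at 89.4 CPM against 0 and 35.4 and Id2 at 59.2 against 86.3 and 124. The Nodal co-receptor gene Tdgf1 stood at 2.23 against 41.1 and 88.5. Imprinted genes were higher in blastoids than at E3.25 in 5 of 5 members, with a median log2 ratio of 2.77 (2.14 to 3.84), including Phlda2 at 496 CPM against 12.3 and the cell cycle inhibitor Cdkn1c at 305 against 53.4. Against E3.5 the 5 members were higher as well, with a median of 0.67 (0.50 to 1.95) where matched random lists had a median of 0.25 and 84.1% of them lay below the list, and Phlda2 stood at 142 CPM and Cdkn1c at 195 there. Cholesterol synthesis genes had a median log2 ratio of 1.79 (1.37 to 2.09) against E3.25 and of 0.18 (-0.097 to 0.98) against E3.5. Against E3.5, 57.9% of matched random lists lay below the list. Its members included Dhcr24 at 404 CPM against 152 and 248 and Fdft1 at 359.6 against 103 and 142. The adhesion gene Epcam (97.2 CPM against 333 and 868) and the chaperone gene Hsp90aa1 (657 against 2450.1 and 5613) stood lower. The E3.5 well held the fewest reads of these wells, and after scaling 3 reads there stood at 53.1 CPM.

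What the blastoid medium did to each stem cell type was a comparison of single wells. Trophoblast stem cells in blastoid medium had more mRNA of progenitor genes than those in TX medium: all 13 measured members of the stemness list were higher, with a median log2 ratio of 0.91 (0.83 to 1.10), and Cdx2 stood at 231 CPM (208 to 256) against 51.4 (40.6 to 64.1). FGF-ERK target genes were higher in 9 of 10 members (median 0.97, 0.74 to 1.19) and integrated stress response genes in 9 of 11 (median 0.90). Among the largest differences were Sema7a (97.2 CPM against 8.56), the placental cathepsin gene Ctsj (99.1 against 9.88), Smox (87.3 against 9.22), and Upp1 (216 against 30.3). Others were Sox3 (198 against 29.0), the retinoic acid hydroxylase gene Cyp26a1 (95.4 against 12.5) and Serpine1 (508 against 93.5). Lower in blastoid medium were Ahnak (85.4 CPM against 522), Igfbp2 (95.4 against 486), Ptms (91.0 against 383), the linker histone gene H1fx (34.9 against 159) and the trophoblast homeobox gene Esx1 (14.3 against 63.2).

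Embryonic stem cells in blastoid medium had more metallothionein mRNA than those in 2i: Mt2 stood at 6436 CPM (6290.4 to 6584) against 430.5 (400.4 to 462) and Mt1 at 1920.2 against 214. T stood at 52.98 CPM (40.5 to 68.0) against 1.14 (0.138 to 4.11) and Evx1 at 63.4 against 1.71, whereas the primed pluripotency list that holds T had 5 members higher and 6 lower (median log2 ratio -0.07). Etv4 (89.5 CPM against 6.82), Jun (228 against 25.6), Nnat (175 against 15.4) and Cdkn1c (304 against 35.3) were higher as well. The FGF-ERK targets were higher in 10 of 10 members (median log2 ratio 0.90), the trophectoderm core list in 12 of 14 (median 1.35, 1.03 to 1.62), primitive endoderm genes in 12 of 14 (median 1.06) and Wnt targets in 4 of 5 (median 1.90). The feeder fibroblast list was higher in 6 of 8 members too (median 0.84, 0.42 to 1.10), and collagen genes went both ways, with Col1a2 at 64.3 against 35.8 CPM and Col3a1 at 17.4 against 52.9. Naive pluripotency genes were lower in 14 of 19 members, with a median of -0.40 (-0.58 to -0.30). The secreted glycoprotein gene Spp1 (9.55 CPM against 100.1), Kdm5b (14.8 against 86.4) and the mismatch repair genes Msh2 (46.9 against 227) and Msh6 (21.7 against 112) were lower.

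Which genes separate embryonic from trophoblast stem cells was tested with the wells of both media as replicates, 2 against 2. Embryonic stem cells had higher mRNA of Dppa5a, a naive pluripotency gene, at 2809 ± 67.6 CPM against 58.1 ± 1.79 (SD, n = 2; log2 fold change 5.62 ± 0.31 SE, adjusted p = 2.0e-05) and Pou5f1 higher by 4.54 ± 0.35 (adjusted p = 0.00027). Trophoblast stem cells had higher mRNA of Gata3, a trophectoderm transcription factor, which differed by -3.59 ± 0.50 (adjusted p = 0.0052), of Cdx2 at -3.86 ± 0.97 (adjusted p = 0.048) and of Igf2 at -4.02 ± 0.49 (adjusted p = 0.0035). In all, 199 of 7965 tested genes were higher in embryonic and 204 higher in trophoblast stem cells.

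Besides Dppa5a, the 12 largest positive differences were in Tdh, which encodes threonine dehydrogenase (chromosome 14, 63492347 to 63509092 in mm10; 808 ± 242 CPM against 12.9 ± 8.62, log2 fold change 6.27 ± 0.58, adjusted p = 0.00053), Pdzd4, Rbmxl2, Ifitm1, Gdf3, Klf2, Gsta4, Stmn2, Pycard, Mylpf and Fgf4, with log2 fold changes from 6.07 ± 1.08 for Pdzd4 to 4.82 ± 0.98 for Fgf4. The 12 largest negative differences ran from Lcp1 (-4.44 ± 0.62) through Dgat2, Nat8l, the protease gene Htra1 (-4.13 ± 0.37, adjusted p = 0.00048), C1qtnf6, Smad6, Cd82, Igf2, Epn3, Gm1673 and Cdx2 to Dysf (-3.84 ± 0.79).

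Of 17 naive pluripotency genes 7 were higher over all genes, and 10 were higher when adjusted over the list alone. Their set test gave an adjusted p of 9.0e-13 with the preset correlation and an adjusted p of 0.444 with an estimated correlation. Klf2 (5.25 ± 0.57) and Gdf3 (5.33 ± 0.65) were among the 7. Of 14 trophectoderm core genes 7 were lower in embryonic stem cells, or 13 adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.444 with an estimated correlation), among them Id2 (-2.62 ± 0.43), Krt18 (-2.63 ± 0.53) and Krt7 (-2.59 ± 0.54). The stemness list had 4 of 12 lower, or 8 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.480 with an estimated correlation), with Ddah1 at -3.49 ± 0.43, Rhox6 at -3.66 ± 0.49 and Elf5 at -3.62 ± 0.79. The differentiation list had 6 of 10 lower, or 7 adjusted over the list alone (camera adjusted p = 4.98e-06, and adjusted p = 0.444 with an estimated correlation), with Cited1 at -3.71 ± 0.48, Rhox9 at -3.54 ± 0.46, Hand1 at -3.62 ± 0.59 and the gelatinase gene Mmp9 at -3.67 ± 0.73.

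Nodal, Tdgf1, Lefty2 and Lefty1 were the 4 of 7 Nodal-SMAD targets that were higher in embryonic stem cells, by 3.66 ± 0.48, 4.11 ± 0.71, 3.97 ± 0.68 and 2.86 ± 0.69. Adjusted over the list alone, 4 were higher and 3 lower (camera adjusted p = 0.127). Of 9 BMP-SMAD targets, Hand1, Id2 and Smad6 (-4.05 ± 0.94) were lower, with 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0198, and adjusted p = 0.456 with an estimated correlation). Igf2, Peg10 (-2.77 ± 0.60) and Grb10 (-2.05 ± 0.47) were the 3 of 11 imprinted genes that were lower, with 8 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00591, and adjusted p = 0.456 with an estimated correlation). Of 20 proliferation genes Mcm3 (1.87 ± 0.38) and Ccnd1 (1.78 ± 0.45) were higher, and 5 were adjusted over the list alone (camera adjusted p = 0.0240, and adjusted p = 0.444 with an estimated correlation). Collagen genes of the feeder fibroblast list were higher in the embryonic wells, namely Col3a1 (36.1 against 1.66 CPM), Col1a1 (18.99 against 1.66) and Col1a2 (51.9 against 2.68), 3 of 5 members by either adjustment (camera adjusted p = 0.00208, and adjusted p = 0.444 with an estimated correlation). Col4a2 (-1.95 ± 0.48) and Sparc (-1.63 ± 0.41) were the 2 of 10 primitive endoderm genes that were lower, with 3 adjusted over the list alone (camera adjusted p = 0.0198, and adjusted p = 0.505 with an estimated correlation).

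The STAT3 target (7 members, median log2 fold change -1.25, adjusted p = 0.0409), epithelial junction (16 members, -0.62, adjusted p = 0.00591) and oxidative phosphorylation lists (12 members, 0.35, adjusted p = 0.0301) also passed camera, with 0, 1 (the desmoplakin gene Dsp, -3.09 ± 0.63) and 0 members past the test over all genes, and 2, 1 and 0 adjusted over the list alone. With an estimated correlation their adjusted p values were 0.445, 0.444 and 0.444, and 0 of the 12 lists past camera passed. At 2 residual degrees of freedom few lists could pass that form of camera, so it cannot decide whether the lists differ. In all 12 the median, the mean and the test had the same sign. By fry, signalling ligands passed (adjusted p = 0.0256; camera adjusted p = 0.127), with Nodal, Gdf3, Fgf4 and Lefty1 higher, Wnt7b (-3.69 ± 0.54) and Wnt6 (-3.30 ± 0.52) lower and 3 of 9 members past neither, or 5 higher and 2 lower adjusted over the list alone. The wells of the types did not overlap for 3940 genes, 49.5%, where chance gives 33.3%. Each type's 2 wells differed in medium. The count of 403 genes became 855 without the embryonic stem cells in blastoid medium, with 360 shared, and 300 without those in 2i, with 203 shared. It became 271 without the trophoblast stem cells in TX medium, with 193 shared, and 277 without those in blastoid medium, with 187 shared. In each of these fits 1 type had 1 well, so the spread came from the other type alone.

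Whether Bmp4 and Nodal change trophospheres was tested with 2 libraries per condition. Id2, a direct target of BMP signalling, rose with Nodal (729 ± 21.1 against 457 ± 54.5 CPM, SD, n = 2; log2 fold change 0.67 ± 0.12 SE, adjusted p = 0.044) and with both ligands (839 ± 14.3 CPM; 0.88 ± 0.13, adjusted p = 0.0091), and was 0.52 ± 0.13 with Bmp4 alone (adjusted p = 0.18). With both ligands Slc22a3, an organic cation transporter gene, rose by 1.68 ± 0.27 (adjusted p = 0.014) and Cebpb by 1.12 ± 0.21 (adjusted p = 0.025). The copper chaperone gene Atox1 fell by 1.22 ± 0.17 with both ligands (adjusted p = 0.0091) and by 1.11 ± 0.17 with Nodal (adjusted p = 0.013). The counts of changed genes among 10908 were 0 up and 1 down with Bmp4, 1 up and 10 down with Nodal, and 7 up and 22 down with both.

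The single gene past the test with Bmp4 was Eif3b, a translation initiation factor gene (chromosome 5, 140419305 to 140443358 in mm10), with 139 ± 11.1 CPM against 292 ± 52.4 (-1.06 ± 0.15, adjusted p = 0.0107). Beside the 0 genes that rose by limma voom, 1098 genes had an unadjusted p under 0.05, and limma-trend gave 2 up and 1 down. With no change simulated, voom called a mean of 2.2 genes in this comparison, more than the 1 found. Of 9 BMP-SMAD targets 0 passed over all genes and 2 were higher adjusted over the list alone (median log2 fold change 0.36, camera adjusted p = 0.0150, and adjusted p = 0.627 with an estimated correlation), with Smad6 at 0.65 ± 0.21, Msx2 at 0.36 ± 0.17 and Hand1 at -0.33 ± 0.15. Of 12 oxidative phosphorylation genes 0 passed and 3 were lower adjusted over the list alone (median -0.12, camera adjusted p = 0.0150, and adjusted p = 0.718 with an estimated correlation), with the cytochrome oxidase gene Cox6c at -0.63 ± 0.12 (adjusted p = 0.083).

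With Nodal, S100a11 fell (345 ± 53.4 against 981 ± 450.1 CPM, -1.44 ± 0.21, adjusted p = 0.013), as did Stra13 (-1.004 ± 0.15), Tmem258 (-0.84 ± 0.15), the Golgi calcium pump gene Atp2c2 (-0.83 ± 0.15), the metallothionein gene Mt1 (-0.82 ± 0.14) and Ndufa7 (-0.76 ± 0.14). Hand1 stood at -0.69 ± 0.15 (adjusted p = 0.079) and Cdx2 at 0.68 ± 0.26 (adjusted p = 0.37). The oxidative phosphorylation list had 0 of 12 members past the test and 1 lower adjusted over the list alone (median -0.26, camera adjusted p = 0.04999, and adjusted p = 0.673 with an estimated correlation).

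With both ligands C330027C09Rik (1.01 ± 0.20), Ptms (0.96 ± 0.18) and Tmed7 (0.77 ± 0.15) rose too. S100a11 (-1.37 ± 0.21), the trophoblast surface antigen gene Ly6a (-1.03 ± 0.17, adjusted p = 0.016), Sh3bgrl3 (-1.01 ± 0.16), and Ascc1 (-0.99 ± 0.18) fell. So did the dynein light chain gene Dynlrb1 (-0.90 ± 0.15), Pdrg1 (-0.90 ± 0.18), Stra13 (-0.89 ± 0.15), Atp2c2 (-0.84 ± 0.16), Mea1 (-0.81 ± 0.14), Mt1 (-0.78 ± 0.14) and Sept4 (-0.77 ± 0.13). Of 9 BMP-SMAD targets Id2 rose and 8 did not pass over all genes, with 2 up and 1 down adjusted over the list alone (median 0.63, camera adjusted p = 0.00570, and adjusted p = 0.350 with an estimated correlation), and the list passed fry (adjusted p = 0.0331), which does not compare it with other genes. No member passed over all genes in the imprinted (10 genes, camera adjusted p = 0.00930, 2 higher adjusted over the list alone), oxidative phosphorylation (12 genes, 0.00570, 1 lower), primitive endoderm (12 genes, 0.0346, 3 lower), primed pluripotency (6 genes, 0.0346, 0 either way) and cholesterol synthesis lists (12 genes, 0.0421, 0 either way). With an estimated correlation the adjusted p values of these lists were 0.350, 0.527, 0.425, 0.425 and 0.587. None of the lists past camera in trophospheres passed in that form. At 4 residual degrees of freedom few lists could pass it, so it cannot decide whether the lists differ. Examples were the imprinted Peg10 at 0.80 ± 0.17 (adjusted p = 0.054) and Cdkn1c at 0.55 ± 0.15, and the basement membrane genes Sparc at -0.61 ± 0.14 and Col4a2 at -0.64 ± 0.15.

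No gene passed the test between trophospheres with both ligands and those with Bmp4 alone or with Nodal alone, and the interaction of the ligands passed in 0 genes, each by limma voom and by limma-trend. Without Bmp4 library 2, 10 genes were higher and 15 lower with both ligands than with Bmp4 alone. Genes with an unadjusted p under 0.05 numbered 1040, 290 and 669. Against Bmp4 alone, cholesterol synthesis (median 0.22, camera adjusted p = 0.00426) and imprinted genes (median 0.40, camera adjusted p = 0.00809) passed camera, each with an adjusted p of 0.593 with an estimated correlation. Over all genes 0 of their 12 and 10 members passed, and adjusted over the list alone 0 and 2 were higher, with Dhcr24 at 0.59 ± 0.18, Grb10 at 0.41 ± 0.13 and Cdkn1c at 0.44 ± 0.15.

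The stimulated conditions shared their controls, and the covariance of their log2 fold changes was 0.124 for Bmp4 with Nodal, 0.129 for Bmp4 with both ligands and 0.148 for Nodal with both. Independent conditions simulated with the shared controls gave 0.0987, 0.0982 and 0.0981, and part of the excess may still come from those controls. The correlations were 0.741, 0.710 and 0.825 against 0.758, 0.760 and 0.785 in the simulations, so only that of Nodal with both lay above the simulated one. Control and stimulated wells did not overlap for 39.9% of genes with Bmp4, 40.6% with Nodal and 45.1% with both, where chance gives 33.3%. Between both ligands and Bmp4 alone, where 0 genes passed, the share was 43.7%, and between both and Nodal alone it was 30.8%. A share above 33.3% was thus not particular to comparisons with control. The control libraries were the shallowest, and without control library 1 the counts of changed genes were 0, 0 and 0, whereas without control library 2 they were 17, 50 and 82. In these fits the control had 1 library, so the spread came from the stimulated conditions alone. By limma-trend the counts were 3, 0 and 31.

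How 3D culture differs from 2D culture was asked for each stem cell type in 1 library per culture. Trophoblast stem cells in 3D had less mRNA of progenitor genes and more of trophoblast keratins: Esrrb stood at 78.1 CPM (73.5 to 82.8) in 3D and 428 (416 to 440.4) in 2D, Eomes at 60.3 and 339.5, and Sox2 at 49.8 and 266. The keratin Krt8 stood at 4091 (4057 to 4124) and 375 (363 to 386), and Krt18 at 3913 and 721. Embryonic stem cells in 3D and 2D were closer: of 3750 genes with at least 50 CPM in either culture, 79 were higher and 37 lower in 3D by more than 2-fold over the interval, against 421 and 287 of 4306 genes in trophoblast stem cells. Across 3251 genes the log2 ratios of the types had a Spearman rho of 0.0778 (0.0428 to 0.113).

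Trophoblast stem cells in 3D had the largest ratios for Gjb2, a gap junction gene (454 CPM, 443 to 466, against 3.84, 2.76 to 5.18), Zfp36l3 (396 against 9.31), Serpinb9e (303 against 7.49), Flt3 (112 against 0.548), Arhgef6 (253 against 8.22), and Dnase1l3 (150.1 against 3.01). Next came Lgals3 (1409.7 against 88.3), Plekha6 (107 against 3.29), the carbonic anhydrase gene Car4 (191 against 9.95), the placental gene Plac1 (86.3 against 2.37), Tns4 (125 against 5.48) and Mbnl3 (357 against 26.8). Lower in 3D were Fgfbp1 (9.59 CPM against 207), Nat8l (61.5 against 795), Gm1673 (15.5 against 238), Cyp26a1 (2.93 against 87.8), the ERK phosphatase gene Dusp6 (6.58, 5.31 to 8.07, against 127, 120.1 to 134), and Nr0b1 (0.787 against 56.4). So were Sox3 (3.58 against 79.9), Bmp4 (9.02 against 133), Mest (31.8 against 311), Pck2 (7.37 against 97.1), the FGF antagonist gene Spry4 (2.29 against 52.5) and Mthfd2 (26.5 against 234).

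Stemness genes were lower in 3D trophoblast stem cells in 10 of 13 members, with a median log2 ratio of -2.22 (-2.30 to -2.09). FGF-ERK targets were lower in 10 of 11 (median -2.03, -2.13 to -1.82), with the immediate early gene Fos as the exception at 188 against 31.0 CPM. Cholesterol synthesis genes were lower in 12 of 12 (median -1.25, -1.31 to -1.19), including Hmgcs1 at 122 against 379.5 CPM, and proliferation genes in 20 of 20 (median -0.79, -0.87 to -0.76), including Top2a at 286 against 502. Primed pluripotency genes were lower in 5 of 5 (median -2.55) and DNA methylation genes in 6 of 8 (median -0.73). Differentiation genes were higher in 8 of 12 (median 0.82, 0.79 to 0.87), with Rhox9 at 913 against 251 CPM and Hand1 at 924 against 372. Imprinted genes were higher in 10 of 13 (median 1.44, 1.28 to 1.47), with Peg10 at 1553 against 219 CPM, Cdkn1c at 1049 against 163 and Igf2 at 10058 against 4907. Id2 stood at 211 against 838 CPM. Trophectoderm core genes went both ways, 7 up and 7 down.

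Embryonic stem cells in 3D had higher Dppa5a (1840 CPM, 1814 to 1866, against 748, 733 to 763) and Esrrb (739.7 against 462) and lower Dppa3 (35.7 against 200.4), with 13 of 19 naive genes higher (median log2 ratio 0.14, 0.11 to 0.27). Nodal targets were higher in 7 of 7 members (median 0.70, 0.58 to 0.83), with Lefty2 at 279 against 146 CPM, Lefty1 at 139 against 71.0 and Nodal at 83.2 against 49.4. Integrated stress response genes were higher in 10 of 11 (median 0.65, 0.60 to 0.74), with Atf4 at 539.7 against 348 CPM. Cholesterol synthesis genes were lower in 12 of 12 (median -0.95, -0.99 to -0.88), with Fdft1 at 214 against 442 CPM and Fdps at 82.8 against 212. Primed genes were lower in 4 of 6, with Zic2 at 4.22 against 38.2 CPM and Dnmt3b at 177 against 364. Other genes with large ratios were Dusp9 (102 against 10.5 CPM), Mylpf (352 against 59.7), Phlda2 (177 against 31.6) and Etv4 (92.2 against 16.4). Lower were Olig2 (11.4 against 95.3), Vim (49.1 against 199), Scd1 (43.5 against 168), Mycn (86.4 against 311) and Tuba1a (217 against 748). The median log2 ratio of all 3750 genes was -0.10.

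The largest ratios in embryonic stem cells also held genes of other cell types: in 3D the class II antigen presentation gene H2-Ab1 stood at 105 CPM against 0.623, H2-Eb1 at 88.0 against 0.390 and the collagen gene Col3a1 at 86.4 against 0, where 0 allows up to 0.287 CPM. Fibroblast genes of a list of 11 came to 234 CPM in the kept wells of this library, against 1.71 in the 2D library. Cluster 8 of the single cells held 24 cells, all of this library, and was led by 8 fibroblast markers beside 5 epiblast or embryonic stem cell markers. By the run codes in the library names, the 3D and the 2D library of each type came from different sequencing runs, so that culture and run cannot be told apart.

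Which classes of cells the dissociated blastoids held was read from clusters of all 6 single-cell libraries together. Trophoblast-like cells made up 179 of 294 cells of blastoid library 1, or 60.9% (Clopper-Pearson 95% interval 55.0 to 66.5), and 103 of 279 cells of library 2, or 36.9% (31.2 to 42.9). Epiblast-like cells made up 33.7% (28.3 to 39.4) and 58.1% (52.0 to 63.9), and 5.44% and 5.02% of cells lay in unnamed clusters. The trophoblast-like clusters 0, 2 and 3 took in 91.99% of trophoblast stem cells in 3D and 95.7% in 2D, and the epiblast-like clusters 1, 4 and 5 took in 89.6% of embryonic stem cells in 3D and 98.5% in 2D. The class of the 3D embryonic stem cells depended on the clustering: at resolution 0.3 a cluster with 280 of the 288 cells was unnamed, and thinned to 2000 transcripts 267 cells lay in an unnamed cluster.

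Within these classes the libraries parted, and the part of sequencing run in this was not tested. Of the trophoblast-like blastoid cells, 134 and 81 lay in cluster 3 and 39 and 22 in cluster 0, whereas 261 cells of the 3D trophoblast stem cells lay in cluster 0 and 278 of the 2D cells in cluster 2. Of the epiblast-like blastoid cells, 98 and 161 lay in cluster 4, whereas 256 embryonic stem cells in 3D lay in cluster 5 and 324 in 2D in cluster 1. No cluster took its name from primitive endoderm genes. The unnamed cluster 7, with 26 of its 27 cells from 3D trophoblast stem cells, was led by 3 of them beside 7 trophoblast markers. Cells with at least 3 of 6 primitive endoderm genes (Gata6, Gata4, Sox17, Sox7, Pdgfra and Foxa2) were 2.38% (0.963 to 4.84) and 1.08% of the blastoid libraries, at median depths of 31377 and 36819 transcripts. The share was 2.08% and 1.99% of trophoblast stem cells in 3D and 2D, 0.912% of embryonic stem cells in 2D and 0 of 288 in 3D, which allows up to 1.27%. The intervals of the blastoid libraries overlapped those of the trophoblast stem cells (0.839 to 4.23 in 3D).

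How blastoid cells differed from stem cells of their class was described in both blastoid libraries. By the library names, the 3D embryonic and 2D trophoblast plates came from a sequencing run without a blastoid plate. Against these plates, run and origin of the cells cannot be told apart. Trophoblast-like cells (clusters 0, 2 and 3) had more progenitor mRNA than 3D trophoblast stem cells: Esrrb stood at 238 and 234 CPM in the blastoid libraries, 85.4 in 3D and 429 in 2D, Eomes at 263 and 265 against 65.7 and 343, and Sox2 at 311 and 230.5 against 54.0 and 262. Keratins lay between the cultures, with Krt8 at 941 and 1330.3 CPM against 3917 in 3D and 378 in 2D. Of 4373 genes, Apoe (341 and 323 CPM against 48.5 and 45.4) and Eras (86.0 and 81.3 against 28.5 and 17.4) were higher than in both cultures by more than 2-fold over the interval. Lower were Tgm2 (17.8 and 8.16 against 177 and 66.6), the retinol-binding gene Rbp1 (59.8 and 61.3 against 147 and 152) and Tuba1a (60.5 and 71.9 against 193 and 165).

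Against 3D trophoblast stem cells, stemness genes were higher in 10 of 12 members in each blastoid library (median log2 ratio 1.502, 1.37 to 1.63, and 1.63, 1.51 to 1.69) and proliferation genes in 19 of 19 (median 0.81 and 0.76), with Top2a at 505 and 545 CPM against 311. Imprinted genes were lower in 8 of 12 (median -0.63 and -0.50), with Peg10 at 200.2 and 296 against 1271 CPM, and the immediate early and heat shock genes in 8 of 10 (median -0.75 and -0.66). Against 2D trophoblast stem cells, FGF-ERK targets were lower in 10 of 11 (median -1.03 and -0.98), with Dusp6 at 22.9 and 40.0 against 126.2 CPM and Egr1 at 6.06 and 5.33 against 90.3. Cholesterol synthesis genes were lower in 12 of 12 (median -0.99 and -1.08), with Hmgcs1 at 165 and 171 against 379 CPM. Stemness genes had medians of -0.13 and -0.08 and proliferation genes of -0.06 in each library against 2D.

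Epiblast-like cells (clusters 1, 4 and 5) of both blastoid libraries had 59 of 4164 genes higher and 31 lower than in both embryonic stem cell cultures. The matrix gene Tinagl1 stood at 218 and 168 CPM against 2.18 in 3D and 2.43 in 2D, and the imprinted RNA H19 at 1921 and 1224 against 8.43 and 48.5. In trophoblast-like cells of the same libraries Tinagl1 stood far higher, at 1408 and 1466 CPM, as did H19, at 15326 and 13255. The Nodal antagonist genes Lefty2 (11.7 and 16.02 CPM against 280 and 147) and Lefty1 (12.1 and 15.1 against 146 and 71.1) were lower, as was Bmp4 (7.58 and 15.3 against 70.7 and 100). Other genes higher than in both cultures were Igf2 (377 and 303 CPM against 7.07 and 16.6), S100a1 (105 and 107 against 5.10 and 2.04), Bhlhe41 (60.3 and 76.3 against 4.79 and 1.17), and Eps8l2 (105 and 104 against 11.4 and 5.09). The same held for the kinesin gene Kif1a (56.8 and 55.9 against 5.31 and 1.88), the meiotic gene Sycp3 (84.9 and 90.8 against 13.4 and 1.41), Cln6 (61.0 and 79.2 against 11.2 and 8.53), Gsn (55.0 and 55.2 against 10.2 and 2.11), Krt18 (98.9 and 123 against 21.6 and 10.2) and Hand1 (65.6 and 50.1 against 0 and 1.80). Lower were Enox1 (6.06 and 12.4 CPM against 89.6 and 90.7), Gbx2 (7.20 and 4.37 against 55.7 and 91.1), Lgals9 (20.1 and 17.3 against 112 and 94.7), and Zic3 (31.8 and 33.1 against 134 and 145). So were the cyclin gene Ccne1 (47.0 and 53.9 against 221 and 207), Hsd17b14 (46.6 and 65.4 against 317 and 247), Tcf15 (15.2 and 14.6 against 184 and 64.0), the Wnt inhibitor gene Notum (4.17 and 4.92 against 28.9 and 85.4) and L1td1 (99.7 and 102 against 341 and 363).

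Naive pluripotency genes had medians below the stem cell level in epiblast-like cells, at -0.33 and -0.26 against 3D and -0.21 and -0.39 against 2D. Dppa5a stood between the cultures, at 1270.3 and 1346 CPM against 1838 and 748. Proliferation genes were lower in 18 and 20 of 20 members against 3D (median -0.44 and -0.65) and in 20 of 20 against 2D (median -0.62 and -0.94). Cell cycle inhibitors and p53 targets were higher in 8 of 10 in each comparison (median 0.58 and 0.62 against 3D, 0.72 and 0.61 against 2D), with Cdkn1a at 301 and 236 CPM against 93.8 and 109 and Ccng1 at 519 and 452 against 221 and 222. Nodal targets were lower in 7 of 8 against 3D (median -0.61 and -0.68), and against 2D 4 of 8 were lower. Cholesterol synthesis genes were lower in 12 of 12 against each culture (median -0.65 and -0.47 against 3D, -1.71 and -1.52 against 2D), with Fdft1 at 149 and 181 CPM against 218 and 443. Imprinted genes were higher in 10 of 12 (median 0.95 and 0.76 against 3D, 1.20 and 1.36 against 2D). The trophectoderm core list was higher in 9 of 10 and 8 of 9 against 3D. Trophoblast genes absent from the stem cells and not among the 59 stood in these cells at a median 3.62% and 2.74% of their level in trophoblast-like cells of the same library. Igf2 stood at 6.06 and 5.39%, Krt18 at 6.96 and 6.62% and Hand1 at 7.47 and 4.54%. H19 stood at 12.2 and 8.87% and Tinagl1 at 15.3 and 11.3%, where the highest of those trophoblast genes stood at 6.18 and 6.63%.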

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

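The test of same-numbered wells, the test of the mix of lists and the reference without the tested genes were chosen only after the result was seen, and the other tests before.

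Embryonic and trophoblast stem cells differed in how list medians stood in 3D over 2D. The embryonic minus the trophoblast median log2 ratio was 1.12 for naive pluripotency genes, -1.01 for BMP-SMAD targets, 2.29 for FGF-ERK targets, 1.14 for integrated stress response genes and 1.04 for DNA methylation genes. These drew attention because the medians of 3D over 2D lay far apart in the types. The differences were not tested, and each rests on 1 library per culture. By the library names the 3D embryonic and the 2D trophoblast library shared a sequencing run. A difference between runs would thus enter the ratios of the types in opposite directions, so culture and run cannot be told apart here.

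Reads without a described condition drew attention because they hold data that no comparison used: 3 wells in the blastocyst and blastoid library and 14 in the stem cell library. In the 3D embryonic stem cell library, wells left out for low depth held 1941 transcripts of the immune list.

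Trophospheres with Nodal and with both ligands had lower mRNA of Atox1 and higher mRNA of Id2 than control, whereas with Bmp4 alone the log2 fold changes of -0.68 (Atox1, adjusted p = 0.196) and 0.52 (Id2, adjusted p = 0.175) did not pass. The log2 fold changes with Bmp4, Nodal and both had a Spearman rho of 0.167, 0.181 and 0.172 with transcript length. These values cover 4974 of the more highly expressed genes among the 10908 tested. The covariance of the Bmp4 and Nodal changes beyond that of the shared controls was taken over 4983 of the more highly expressed genes. It would reach 0 after thinning if the lower depth of the control libraries were the cause, and it was 0.0171 (0.0143 to 0.0202). If transcript length were the cause, it would reach 0 after the trend was removed, and it was 0.0149 (0.0122 to 0.0175) over 4974 genes. These intervals come from resampled genes and leave out the spread between libraries, and the control term rests on 1 pair of libraries. The excess stayed above 0 after either step, but for that reason the test cannot decide on those causes. A response to the ligands or another difference between the libraries remains open as well.

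The 3D embryonic stem cell library held transcripts of a kind scarce in the 2D library. There 0 of 11 fibroblast, 0 of 12 immune and 0 of 8 measured mammary list genes reached 10 CPM. The bulk embryonic wells did hold mRNA of fibroblast collagen genes. Kept wells of the 3D library held 234 CPM of the fibroblast list, 463 of the immune list and 107 of the mammary list. Among these genes were H2-Ab1 at 105 CPM and Col3a1 at 86.4. Whole cells of another tissue remain a hypothesis: 1 kept well took 6.09% of its transcripts from the lists, as that cause predicted, and 28 of 82 left-out wells with at least 100 transcripts took over 5%, up to 22.5%. Free RNA in the suspension was argued against as the main source in wells with at least 10 list transcripts. Of these 209 wells 158, 75.6% (69.2 to 81.3), took at least 90% of them from 1 list. Wells with fewer were outside this test, so free RNA beside another source stays open. Immune, mammary and fibroblast transcripts lay in 228, 178 and 133 of 288 kept wells, against 35, 1 and 22 of 329 in 2D. Reads of another plate of the run, as read from the library names, stay open: the correlation of 0.269 with same-numbered wells of the 2D trophoblast plate (shuffled wells -0.0983 to 0.0964) says nothing on the source, since that plate held 3.93, 14.6 and 2.74 CPM of the lists, and no other plate of the run was in the data.

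Genes higher in epiblast-like blastoid cells than in embryonic stem cells could come from RNA of the trophoblast-like cells. The genes stood at a median 16.9 times (13.2 to 22.1) the share that trophoblast genes absent from stem cells took, which argues against that cause for most of the 59 genes. Of the 59, 2 were themselves among the trophoblast genes of each library; with these left out of the reference the median was 20.6 times (15.2 to 27.0). Hand1, Igf2 and Krt18 then stood at or below 2 times the reference in the library where each stood lower, so these 3 may come from such RNA. Tinagl1 stood at 4.13 and H19 at 3.23 times it by the same measure, so part of their level may come from it too.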

How the results depend on the processing

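The limma-trend test, thinned reads, the medium as a term and the wells with other cell types left out were chosen only after the result was seen. No DESeq2 Wald test was run. No paired analysis was possible because the trophosphere conditions share no replicate numbers. Both stem cell types had 1 well in blastoid medium and 1 in a medium of their own, so a term for blastoid medium was fitted instead. Leaving out 1 replicate left 1 library in its group, so the spread then came from the other groups of the fit alone. Unless stated, the cause was not tested.

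Embryonic minus trophoblast stem cells gave 199 genes higher and 204 lower. Library totals gave 124 higher. The medium as a term gave 315 lower, and of its 609 genes 397 were shared with the 403. Leaving out 1 replicate gave 76 to 398 higher and 89 to 457 lower: without trophoblast stem cell replicate 1 76 were higher, without trophoblast stem cell replicate 2 94, without embryonic stem cell replicate 1 89 were lower, and without embryonic stem cell replicate 2 398 were higher and 457 lower. Of the 403 genes, 193, 187, 203 and 360 were shared with these fits. Of 12 lists past camera, 0 passed with an estimated correlation and 0 by fry. By fry 1 list passed, signalling ligands, which had not passed camera.

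Bmp4 minus control trophospheres gave 0 genes higher and 1 lower. Thinned reads gave 3 higher and 4 lower, limma-trend 2 higher, and only the 2 conditions in the fit 0 lower. Leaving out 1 replicate gave 0 to 2 higher and 0 to 19 lower: 2 higher without Bmp4 replicate 2, Nodal replicate 1 or Nodal replicate 2, and, for lower genes, 0 without control replicate 1, 17 without control replicate 2, 0 without Bmp4 replicate 1, 19 without Bmp4 replicate 2, 5 without Nodal replicate 1 and 5 without Nodal replicate 2. Of the lists past camera, 0 passed with an estimated correlation and 0 by fry.

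Nodal minus control trophospheres gave 1 gene higher and 10 lower. Genes higher numbered 23 with no expression filter, 0 with only the 2 conditions in the fit, 3 with median-of-ratios scaling, 0 with the 10 CPM filter, 3 with thinned reads and 0 by limma-trend. Genes lower numbered 165, 0, 19 and 3 in the first 4 of these, 4 with library totals and 0 by limma-trend. Leaving out 1 replicate gave 0 to 5 higher and 0 to 46 lower: 0 and 0 without control replicate 1, 4 and 46 without control replicate 2, 5 and 23 without Bmp4 replicate 1, 3 and 21 without Bmp4 replicate 2, 0 and 1 without Nodal replicate 1, 3 and 6 without Nodal replicate 2, and 0 and 3 without either replicate of Bmp4 with Nodal. Of the lists past camera, 0 passed with an estimated correlation and 0 by fry.

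Bmp4 with Nodal minus control trophospheres gave 7 genes higher and 22 lower. Only the 2 conditions in the fit gave 13 and 38, thinned reads 11 and 14, library totals 12 and 13, and limma-trend 17 and 14. Leaving out 1 replicate gave 0 to 13 higher and 0 to 69 lower: 0 and 0 without control replicate 1, 13 and 69 without control replicate 2, 13 and 43 without Bmp4 replicate 1, 12 and 36 without Bmp4 replicate 2, 11 higher without Nodal replicate 2, 1 and 0 without Bmp4 with Nodal replicate 1, and 0 and 0 without Bmp4 with Nodal replicate 2. Of the 29 genes, 20 were shared with limma-trend and 18 with thinned reads. Of the lists past camera, 0 passed with an estimated correlation and 1 by fry.

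Bmp4 with Nodal minus Bmp4 trophospheres gave 0 genes, and library totals gave 1 higher. Leaving out 1 replicate gave 0 to 10 higher and 0 to 15 lower, with 10 and 15 without Bmp4 replicate 2; 1 and 2 without control replicate 1 and without control replicate 2; 3 lower without Bmp4 replicate 1; 3 higher without Nodal replicate 1 and without Nodal replicate 2; and 1 higher without Bmp4 with Nodal replicate 1. Of the lists past camera, 0 passed with an estimated correlation and 0 by fry. Bmp4 with Nodal minus Nodal trophospheres gave 0 to 1 genes higher, with 1 without Bmp4 with Nodal replicate 1. The interaction of Bmp4 and Nodal gave 0 to 2 higher and 0 to 1 lower, with 2 and 1 without Bmp4 replicate 2 and 1 higher without Bmp4 with Nodal replicate 1.

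The trophoblast stemness median log2 ratio, trophectoderm stem cells 3D over 2D, was -2.22, and became -2.37 with 1 CPM added and -1.83 with 20 CPM added. For trophoblast-like cells over trophectoderm stem cells 3D it was 1.63 in blastoid library 2, and became 1.74 with at least 1000 transcripts, 1.75 with at least 4000, 1.73 with cells of high depth left out and 1.74 at Leiden resolution 1.0. In blastoid library 1 it was 1.502, and became 1.71 with cells of high depth left out.

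The class of the 3D embryonic stem cells depended on the clustering. At Leiden resolution 0.3 a cluster with 280 of the 288 cells was unnamed and 7 lay in an epiblast-like cluster. Thinned to 2000 transcripts, 267 lay in an unnamed cluster.

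Some medians changed sign. The Nodal-SMAD targets median log2 ratio, blastoids over E3.25 blastocysts, went from -1.72 (-2.09 to -1.07) to 0.15 with no expression filter and to -0.0447 with the 10 CPM filter. The germline median of trophectoderm stem cells 3D over 2D went from 0.10 to -0.41 as a mean over cells. For embryonic stem cells 3D over 2D, the primitive endoderm median went from -0.59 to 0.0468 as a mean over cells, and the hypoxia and glycolysis median from -0.09 to 0.0019 as a mean over cells and to 0.17 with wells with 3 list transcripts of other cell types left out. The cavity and transport median log2 ratio, trophoblast-like cells of blastoid library 1 over trophectoderm stem cells 3D, went from 0.12 to -0.0528 with at least 1000 transcripts, -0.0529 with at least 4000, -0.0443 with cells of high depth left out and -0.0514 at Leiden resolution 1.0. The trophoblast differentiation median of the same cells over 2D went from 0.22 to -0.10 with cells of high depth left out.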

Other observations

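Nothing in this part was tested, and all of it was looked at only after the result was seen.

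In blastoid library 1, 2 cells held 92 of its 122 Gata6 transcripts and 43 of its 48 Sox17 transcripts. Each of these cells held at least 10 transcripts of both genes, and 0 cells of any other single-cell library did. Blastoid library 2 held 16 Gata6 transcripts and 1 Sox17 transcript in 279 cells.

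Wells without a described condition held distinct profiles. In wells 20 and 21 of the stem cell library the endoderm genes Sox17 (707 CPM, 669 to 746, and 797, 759 to 837), Gata6 (89.5 and 69.2) and Gata4 (175 and 214) stood high, with the matrix gene Sparc at 8345 and 14475 CPM. Wells 18 and 19 held Pou5f1 at 3606 and 2081 CPM with Dppa5a at 97.8 and 117, whereas wells 14 to 16 held Dppa5a at 3425, 1613 and 1982. Krt8 stood at 5384 and 7095 CPM in wells 8 and 12, with Gata3 at 152 and 194. Wells 2 to 4 of the blastocyst and blastoid library held Krt8 at 2896, 3268 and 2924 CPM and Pou5f1 at 219, 277 and 231. The conditions of these wells were not used here.

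Among epiblast-like blastoid cells the integrated stress response list stood above 2D embryonic stem cells in 10 of 11 members in each library, with medians of 1.07 and 1.25, and primed pluripotency genes stood below in 6 of 6, with medians of -1.33 and -0.88.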
